A study of Mus musculus with 3 samples.

How the data were processed

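Expression was measured on 3 Affymetrix arrays, 1 for each of 3 genotypes of mouse LSK cells: WT, p53 KO, and the double knockout of p53 and Mef (DKO). Per the labels' protocols, RNA was purified on RNeasy columns and labelled with biotin by a single cycle of amplification. The number of animals or sorts behind each array is not given in the sources used here.

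The values are signal intensities on a linear scale, as deposited, for 45101 probe sets on each of the 3 arrays. Per the submitters' processing notes, GCOS and MAS5 were used to make them, with no version stated. The 2% trimmed mean of the signals was 500 on each array, so the deposited intensities already carry global scaling to a common mean. No detection call was used here, and every value column of the table was matched to an array.

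Gene symbols came from the platform annotation and were updated through the Entrez ID where the RefSeq gene table (assembly GRCm38.p6) held it, which was so for 34754 probe sets. That table served for names and for the order of neighbouring genes, and no coordinate is printed because the sources name no build. Of the probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 carried none. A probe set without a name here is unnamed in the table used, not without a gene. The level of p53 itself was not analysed here.

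Signals below the median of all signals on the 3 arrays (110.4) were set to that floor and log2 was taken. Each of 18194 named genes was represented by its single-gene probe set with the highest mean signal. A gene counted as measured when it reached the floor on at least 1 array, which 12597 genes did. A difference is the log2 signal of the array named before "against" minus that of the array named after it, and a difference from an array below the floor is a lower bound, written as "at least". Genes at least 2-fold higher or lower were counted for p53 KO against WT, DKO against WT and DKO against p53 KO.

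With 1 array per genotype no test was made and no p-value is given. For scale, the difference was compared with that of a further probe set of the same gene, where 1 was measured. Pairs of unchanged arrays were also simulated 20 times with noise taken either from the spread between probe sets of a gene or from the spread between both knockout arrays. The latter holds any real difference between those arrays too. The former holds no variation between animals, sorts or labelling reactions. Both were drawn as normal noise from a robust spread, which leaves out the tails of the data. Simulated counts are therefore given for scale and are not those expected between replicate arrays.

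Fixed gene lists, 29 in number with 618 entries, covered p53 targets, stem and progenitor genes, the cell cycle, stress programmes and markers of blood and other cell types, and 569 entries were named on the array. The median log2 difference of each list was placed among those of 10000 random lists of the same size, matched on mean level in 10 bins. That percentile describes these arrays and is not a test. Lists under percentile 2.5 or over 97.5 are called outside the middle 95% of random lists. With 87 list medians, 4.35 would fall outside by chance if lists, and the genes within them, varied independently. Several lists share genes, and genes of the same list may vary together between samples, which random lists leave out. More lists may therefore fall outside with no effect of genotype.

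The lists, the floor, the probe set rule, the fold threshold, the percentile among random lists and the alternatives were chosen before the data were examined. The percentile limits, the simulations' noise, the probe set comparison, the choice of 9 mature lineage lists, the immunoglobulin genes, the neighbours of the p53 gene and the added gene groups of the closing section were chosen afterwards. The text names the 10 highest and 10 lowest genes of each comparison whose brighter array reached the 75th percentile of signals (448.4), without clone or predicted names. It also names up to 4 of the members of each list with the largest differences, Elf4 as a targeted gene, and Gfi1 and Ndn, which the study's paper is known to have examined in these cells.

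Alternatives were rescaling to the 2% trimmed mean, quantile normalization, cyclic loess with 3 iterations, a floor at the 25th or the 75th percentile, a pseudocount of 32 with no floor, the mean over all probe sets of a gene, probe sets unique to a transcript, and thresholds of 1.5-fold and 3-fold. The calculation was tested on simulated data with noise of SD 0.25 on the log2 scale. All 100 genes shifted 4-fold were recovered in each comparison. Of 100 genes shifted 2.83-fold, 95% were recovered for p53 KO against WT, 89% for DKO against WT and 95% for DKO against p53 KO. Among unchanged genes, 38 of 11594, 39 of 11592 and 46 of 11589 were called in the same order of comparisons. That noise was the same at all signal levels, and only genes well over the floor were shifted. These rates check the calculation and do not describe these arrays, where noise taken from the data gave 252 to 314 genes per direction.

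The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.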

Results

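Gene expression was measured in LSK cells, the marker-defined fraction of mouse blood-forming cells that holds haematopoietic stem cells and multipotent progenitors. There were 3 arrays, 1 each for WT cells, cells without p53 (p53 KO) and cells without p53 and the ETS factor Mef, which Elf4 encodes (DKO). The design asks what loss of p53 changes in these cells and what further loss of Mef changes on that background. There were no replicates, so each difference compares a pair of arrays, has no error and was not tested.

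Median signal over 45101 probe sets was 98.0 on the WT array, 105 on the p53 KO array and 129 on the DKO array. Signals at or over the floor of 110.4 came from 47.3%, 48.9% and 53.8% of probe sets. Of 33 genes of other organs on a fixed list, 9, 10 and 14 reached the floor, with median signals of 57.3, 64.6 and 89.0. The ratio of 3' to 5' signal was 8.29, 6.20 and 9.19 for actin and 5.85, 6.61 and 5.90 for Gapdh. The 3' signal thus far exceeded the 5' signal on every array, and whether this bias affects the differences was not tested. Across 12597 measured genes, which are not independent replicates, Pearson's r of log2 signals was 0.952 for WT with p53 KO, 0.957 for WT with DKO and 0.942 for p53 KO with DKO.

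The targeted genes give little check of the labels. The level of p53 itself was not analysed here. Elf4 signal was 57.4 on the WT array, 182 on the p53 KO array and 151 on the array labelled DKO, and its other probe set gave 74.3, 173 and 129. Elf4 was therefore near the floor throughout and was not lower on the array labelled DKO than on the WT array. Whether either probe set lies in the deleted part of the gene is not given in the sources used here, so directions against the DKO array rest on its label. Among known p53 targets, Zmat3, which encodes an RNA-binding zinc finger protein, had signals of 736, 203 and 151 on the WT, p53 KO and DKO arrays. Of other known targets, chosen after their values were seen, Ccng1, which encodes cyclin G1, had signals of 8331, 5006 and 5001, and its other probe sets were also lower on both p53-null arrays, while Cdkn1a ran the other way at 291, 569 and 648. Gfi1, a transcriptional repressor that restrains stem cell proliferation, had signals of 528, 1323 and 1153. Ndn, which encodes the growth suppressor necdin, had signals of 740, 1606 and 1691. By the probe set used for each, Gfi1 and Ndn were thus over 2-fold higher on both p53-null arrays. Log2 differences from WT were 1.32 and 1.13 for Gfi1 and 1.12 and 1.19 for Ndn. The 6 measured Ndn probe sets ranged from 0 to 1.25 on p53 KO and from 0.03 to 1.26 on DKO, so not all reached 2-fold. If p53 activates them, as the study is thought to propose from evidence not examined here, lower values without p53 would be likely. These values run the other way, but they cannot decide the point. There was 1 array per genotype, and markers of mature cells were also higher on the p53 KO array. The p53 gene gives no check here, so directions against WT also rest on the labels of the WT and p53 KO arrays. Both genes were chosen because the study is thought to have examined them, so they are not independent evidence.

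The p53 KO array was compared with the WT array to ask what loss of p53 changes. Marker genes of mature blood cells were higher across many lineages. Ppbp, a platelet chemokine, was the most different gene, at 158 on WT and 3292 on p53 KO (log2 difference 4.38, 20.8-fold). Immediate early genes, led by Fos at 1384 and 5890 (2.09), were higher as a group. Genes of G2 and mitosis were slightly higher as a group, with a median of 0.48. Atp1b2, a sodium pump subunit whose gene lies next to that of p53, was the most reduced, at 3537 on WT and 170 on p53 KO (-4.38).

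In all, 820 genes were at least 2-fold higher and 402 at least 2-fold lower on the p53 KO array. After Ppbp, the highest were Clu, a secreted chaperone (3.57), Lrg1, a glycoprotein of neutrophil granules (3.06), the lectin receptor gene Clec4a3 (2.94) and Apol8 (2.77). Dmtn and Alas2, which encode a red cell membrane protein and the erythroid enzyme that starts haem synthesis, followed at 2.70 and 2.68, and Fn3k was at 2.63. The immunoglobulin genes Iglv1 and Ighg3 were below the floor on the WT array and at least 2.90 and 2.66 higher. After Atp1b2, the lowest were the lectin gene Zg16 (-3.28), the metallothionein gene Mt2 (-2.78), the serine protease gene Hpn (-2.72), the meiotic cohesin gene Rec8 (-2.71) and Nme1, a nucleoside diphosphate kinase (-2.41). Pvt1, a noncoding neighbour of Myc, was at -2.32, the deacetylase gene Sirt2 at -2.26, Ccdc86 at -2.18, and Ccdc68 was lower by at least -2.28.

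Of 29 gene lists, 13 lay above the middle 95% of random lists and 0 below it. The 4 largest medians were those of mature lineage lists, closely followed by the immediate early and stress list (1.03). The monocyte and macrophage list had a median of 1.43, with 13 of 16 measured genes at least 2-fold higher, including the chemokine receptor Ccr2 (2.19), Mpeg1 (1.96) and the clotting factor gene F13a1 (1.88). B cell genes had a median of 1.30 with 9 of 13 at least 2-fold higher, among them the kinase Blk (2.32), the lineage factor Ebf1 (2.28) and the surrogate light chain gene Vpreb1 (2.24). The megakaryocyte list was at 1.08 with 9 of 16 higher by that measure, including Pf4 (1.44) and, by at least 2.06, the integrin Itgb3. Granulocyte genes were at 1.05 with 8 of 16, led by Fcnb (1.91) and the proteases Mmp9 (1.79) and Mmp8 (1.77). All 4 medians were above those of all 10000 random lists. The erythroid median was 0.71, at percentile 99.98, but its members parted, with Alas2 at 2.68 and the membrane protein gene Epb42 at 2.44 and the kinase Sphk1 at -1.73. NK cell genes (0.59, percentile 99.6, led by Ccl5 at 1.83) and dendritic cell genes (0.58, percentile 99.8, led by Itgax at 1.96) were also high, each outside in 6 of 7 alternative settings. T cell genes were not displaced (0.11, percentile 77.6). For mast cells, basophils and eosinophils the median was 0.00, yet 4 of 10 genes were at least 2-fold higher, among them the eosinophil granule genes Epx (1.94) and Prg2 (1.84), and with the floor at the 75th percentile the list lay outside, at 0.96 over 6 measured genes (percentile 99.94).

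Among stress and cell cycle lists, 11 of 20 immediate early and stress genes were at least 2-fold higher and none at least 2-fold lower, with a median of 1.03 that was above all random lists. The list was also high for DKO against the same WT array (0.78). A property of that 1 WT sample cannot be told apart from an effect of genotype. Besides Fos, these included Btg2 (1.66), Klf4 (1.58) and Klf6 (1.57). Of 31 genes of G2 and mitosis, 28 were higher and 3 at least 2-fold, namely the kinesins Kif23 (1.26) and Kif11 (1.04) and Nusap1 (1.25). The G1 and S phase list was at 0.09 (percentile 93.4), where E2f2 stood out at 2.19 beside Ccne2 (1.09) and Rrm2 (1.07). G1 regulators had a median of 0.17 (percentile 90.9), with the cell cycle inhibitor genes Cdkn2d at 2.5, Cdkn2c at 1.25 and Cdkn1b at 1.15 and the cyclin Ccnd3 at 1.46, but with probe sets unique to a transcript the list median was 0.85 over 13 genes, above all random lists. These cell cycle values stood beside the higher mature lineage markers on the same array.

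Stem and progenitor lists were modestly higher, on an array where mature lineage lists such as that of megakaryocytes (1.08) were higher too. Whether mature cells account for part of this was not tested. The stem cell identity list had a median of 0.28 (percentile 99.5). Of its 30 genes 7 were at least 2-fold higher, such as Ctnnal1 (1.39), Fhl1 (1.29), Vwf (1.22) and Cd9 (1.20), and 1 lower, the repressor Gfi1b (-1.42). Another probe set was at 0 for Ctnnal1 and at -0.12 for Fhl1. By sign alone 22 genes were higher and 8 lower, the latter including Kit (-0.99), Mllt3 (-0.30) and Hoxa9 (-0.29). Quiescence genes were at 0.30 (percentile 99.2), with Klf4, Cdkn2c, Nr4a1 (1.15) and Cdkn1b the 4 that were at least 2-fold higher. Klf4 is also on the immediate early list. Stem cell identity and quiescence lists were also high for DKO against the same WT array (0.49 and 0.34). For DKO against p53 KO they lay inside the middle 95% (percentiles 76.9 and 44.3). A property of the 1 WT sample thus cannot be told apart from an effect of genotype for these lists either. The multipotent and lymphoid progenitor list was at 0.33 (percentile 98.4, outside the middle 95% in 3 of 7 alternative settings), where Igll1 (2.45), Blnk (2.13) and Il7r (2.05) are also genes of early B cells. Kit, a marker that defines LSK cells, had signals of 4996 on the WT and 2522 on the p53 KO array.

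The p53 target list as a whole was not lower: its median was 0.23 (percentile 95), or 0.26 (percentile 99.3) with the mean of all probe sets and 0.42 (percentile 99.5) with probe sets unique to a transcript, both outside the middle 95%, with Zmat3 at -1.86, Btg2 at 1.66, Trp53inp1 at 0.99 and Perp at least 1.02. The list of p53 regulators was at 0.02, with the kinase Hipk2 at 1.07 and Prmt5 at -0.84. Apoptosis genes were at 0.18 with Bcl2l1 at 1.5, and interferon response genes at 0.11 with Ifi27l2a at 2.18 and Rsad2 at 2.14. Medians were 0.21 for homing and adhesion (0.44 with a pseudocount and no floor, Vcam1 at 2.35), 0.16 for ETS factors (Ets1 at 1.54), 0.13 for antioxidant genes (Glrx at 1.39), 0.12 for imprinted genes and 0.11 for glycolysis (0.47 with probe sets unique to a transcript, Pkm at 1.31). DNA repair genes were at -0.16, with the end-joining gene Xrcc5 at -1.28. The stroma and endothelium list was at 0.37 (percentile 98.5, outside in 1 of 7 alternative settings), where Vcam1 and Cxcl12 (1.03) led, while genes of other organs were at 0.00 and the sex-linked genes at -0.04.

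Simulated pairs of unchanged arrays gave 253 to 306 genes per direction, against the 820 and 402 observed, but neither noise model measures the variation between replicate arrays. Where a gene had a further measured probe set, it pointed the same way for 427 of 510 genes (83.7%) and was itself at least 2-fold for 172. Atp1b2 was among the exceptions, since its other probe set was near the floor at 121 on WT and 134 on p53 KO. Kif11 (-0.66) and Ccnd3 (-0.12) also had a probe set of opposite sign.

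**Figure D1:**
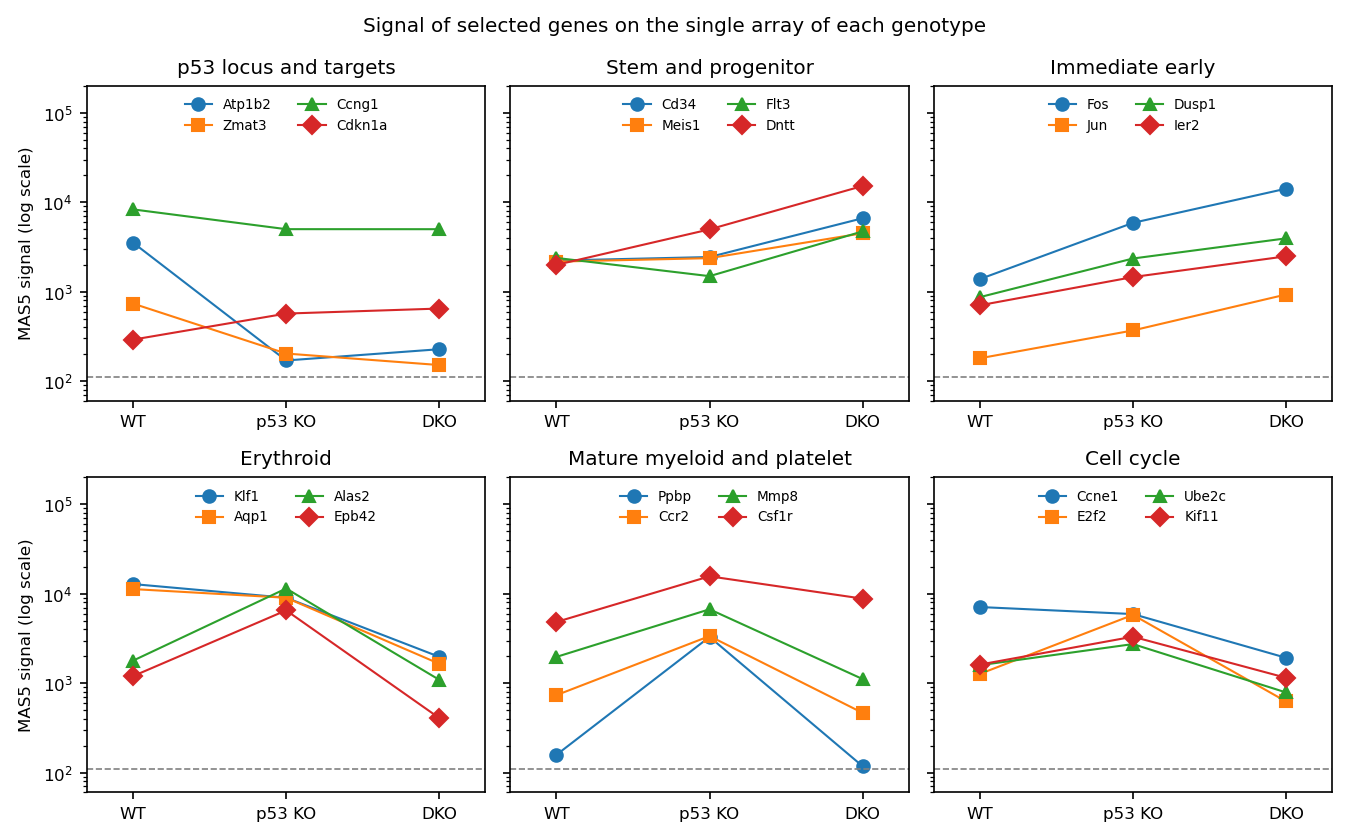
MAS5 signal, on a log scale, of selected genes on the WT, p53 KO and DKO arrays, 1 point per array, with the floor of 110.4 as a dashed line. Mature markers such as Ppbp peak on the p53 KO array at 3292, erythroid Klf1 is lowest on the DKO array at 1972, and Fos is highest there at 14202.

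The DKO array was compared with the WT array to ask what combined loss of p53 and Mef changes. Erythroid genes were lower throughout, with all 17 measured members reduced and a median of -1.56. Immediate early genes and genes of early progenitors were higher, Fos reaching 14202 against 1384 on WT (3.36) and Dntt, the enzyme that adds nucleotides to rearranging antigen receptor genes, reaching 15238 against 1996 (2.93). Genes of G2 and mitosis were lower, with a median of -0.43. Lists of the other mature lineages had medians between -0.33 and 0.48. Some red cell genes were bright on the WT array, such as Ermap at 19247 and Klf1 at 12847. The arrays give no share of cells per type. A different cell make-up of the WT and DKO sorts therefore cannot be told apart from an effect of genotype.

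On the DKO array 657 genes were at least 2-fold higher and 390 at least 2-fold lower than on WT. The highest was Prm1, a sperm protamine, at 1718 against 3.48 on WT and 2.29 on p53 KO, which is at least 3.96. Fos and Dntt came next, then the meiotic genes Msh5 (at least 2.88) and Ccnb1ip1 (at least 2.55), Sapcd1 (2.70), Cuedc1 (2.39), the carbonic anhydrase gene Car3 (2.39), Rnf157 (2.37) and the AP-1 gene Jun (2.37). The lowest was again Atp1b2 at 227 (-3.96), followed by Crip2 (-3.08), the copper pump gene Atp7b (-2.93), the anion transporter gene Slc26a1 (-2.91), Tlcd4 (-2.91), Garem1 (-2.88), Epdr1 (-2.86) and Pvt1 (-2.79). Aqp1, the red cell water channel, was at -2.78 and the matrix protease gene Mmp14 at -2.77.

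Of the 29 lists, 8 lay above the middle 95% of random lists and 6 below it. In the erythroid list, 13 of 17 genes were at least 2-fold lower, below all 10000 random lists. Klf1, the master regulator of red cell genes, had signals of 12847 on WT and 1972 on DKO (-2.70), and Ermap was at -2.70 and Sphk1 at -2.58. The multipotent and lymphoid progenitor list had a median of 0.92, above all random lists, with 7 of 16 at least 2-fold higher, including Ctla2a (2.06), the receptor Cd27 (1.65) and Il7r (1.58). The stem cell identity list was also above all random lists at 0.49, with Fhl1 at 1.81, the surface marker Cd34 at 1.57 and Gfi1b at -1.74. Quiescence genes were at 0.34 (percentile 99.5, outside in 6 of 7 alternative settings), with 3 of 25 at least 2-fold higher, namely Egr1 (1.61), Satb1 (1.22) and Hif1a (1.08). Egr1 is also on the immediate early list. Stem cell identity and quiescence lists were high for p53 KO against the same WT array too (0.28 and 0.30). ETS factors, the family of Mef, had a median of 0.53 (percentile 99.92), and Erg (1.25), Spi1 (1.18), Elk3 (1.17) and Fli1 (1.12) were each over 2-fold higher. Homing and adhesion genes were at 0.49 (percentile 99.89, outside in 5 of 7 alternative settings), with Icam1 at 1.44.

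Immediate early and stress genes had a median of 0.78, above all random lists, with 10 of 20 at least 2-fold higher, among them Jun, the phosphatase Dusp1 (2.18) and Ier2 (1.82). Of 31 genes of G2 and mitosis, 28 were lower, the centromere histone Cenpa (-1.14) and the ubiquitin-conjugating enzyme Ube2c (-1.01) by at least 2-fold, and the median was below all random lists. G1 and S phase genes were at -0.25 (percentile 1.74), with cyclin E gene Ccne1 at -1.89, Orc1 at -1.08 and E2f2 at -1.02. Antioxidant genes were at -0.29 (percentile 0.720, outside in 6 of 7 alternative settings), with Gclm (-1.35), Gpx4 (-1.10) and Nqo1 (-1.08) at least 2-fold lower. DNA repair genes were at -0.21 (percentile 2.20, outside in 3 of 7 alternative settings), none by 2-fold, with Xrcc5 at -0.99. The G1 regulators were at -0.03, where Cdkn1a, the p53 target that inhibits cyclin-dependent kinases, was at 1.15.

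Granulocyte genes had a median of -0.33 (percentile 1.69, outside in 3 of 7 alternative settings) and a mean of -0.01, with members on both sides. The primary granule genes Ctsg (1.54) and Elane (1.53) were higher, while the later granule genes Camp (-1.19) and Ltf (-1.16) were lower. Medians for the other blood lineages were 0.48 for B cells (percentile 95.5, Vpreb1 at 1.14), 0.30 for megakaryocytes (percentile 92.0, Selp at 1.46), 0.29 for T cells, 0.27 for mast cells, basophils and eosinophils (Prg2 at -2.17, Cpa3 at 1.72), 0.05 for NK cells, 0.03 for dendritic cells and -0.06 for monocytes and macrophages. The p53 targets were at -0.02, with Zmat3 at -2.28, Gadd45a lower by at least -1.30, Sesn1 at 1.27 and Perp at least 1.44. Apoptosis genes were at 0.19 (Bcl2 at 1.19, Bcl2l11 at -1.11), imprinted genes at 0.21 (Grb10 at -1.36), glycolysis at 0.10 (0.23 with the mean of all probe sets and 0.47 with probe sets unique to a transcript, Slc2a1 at 1.17), p53 regulators at 0.04 and interferon response genes at 0.04. The stroma and endothelium list was at 0.56 (percentile 99.8, Pdgfrb at 1.94) and genes of other organs at 0.46 (percentile 97.9), both on the array with the highest median signal, and both lay inside the middle 95% in 6 of 7 alternative settings. Sex-linked genes were at 0.59.

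The balance of higher and lower genes depended on scaling, from 657 and 390 (62.8% higher) to 463 and 475 (49.4%) after quantile normalization and 432 and 487 (47.0%) after cyclic loess, against 252 to 305 per direction in simulated unchanged arrays. Further probe sets pointed the same way for 381 of 472 genes (80.7%). They were at least 2-fold the same way for 118 and at least 2-fold the opposite way for 4. Named genes with a probe set of opposite sign included Atp7b (0.77), Pvt1 (0.45), Car3 (-0.11), Rnf157 (-0.24), Orc1 (0.23) and Grb10 (0.14).

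**Figure D2:**
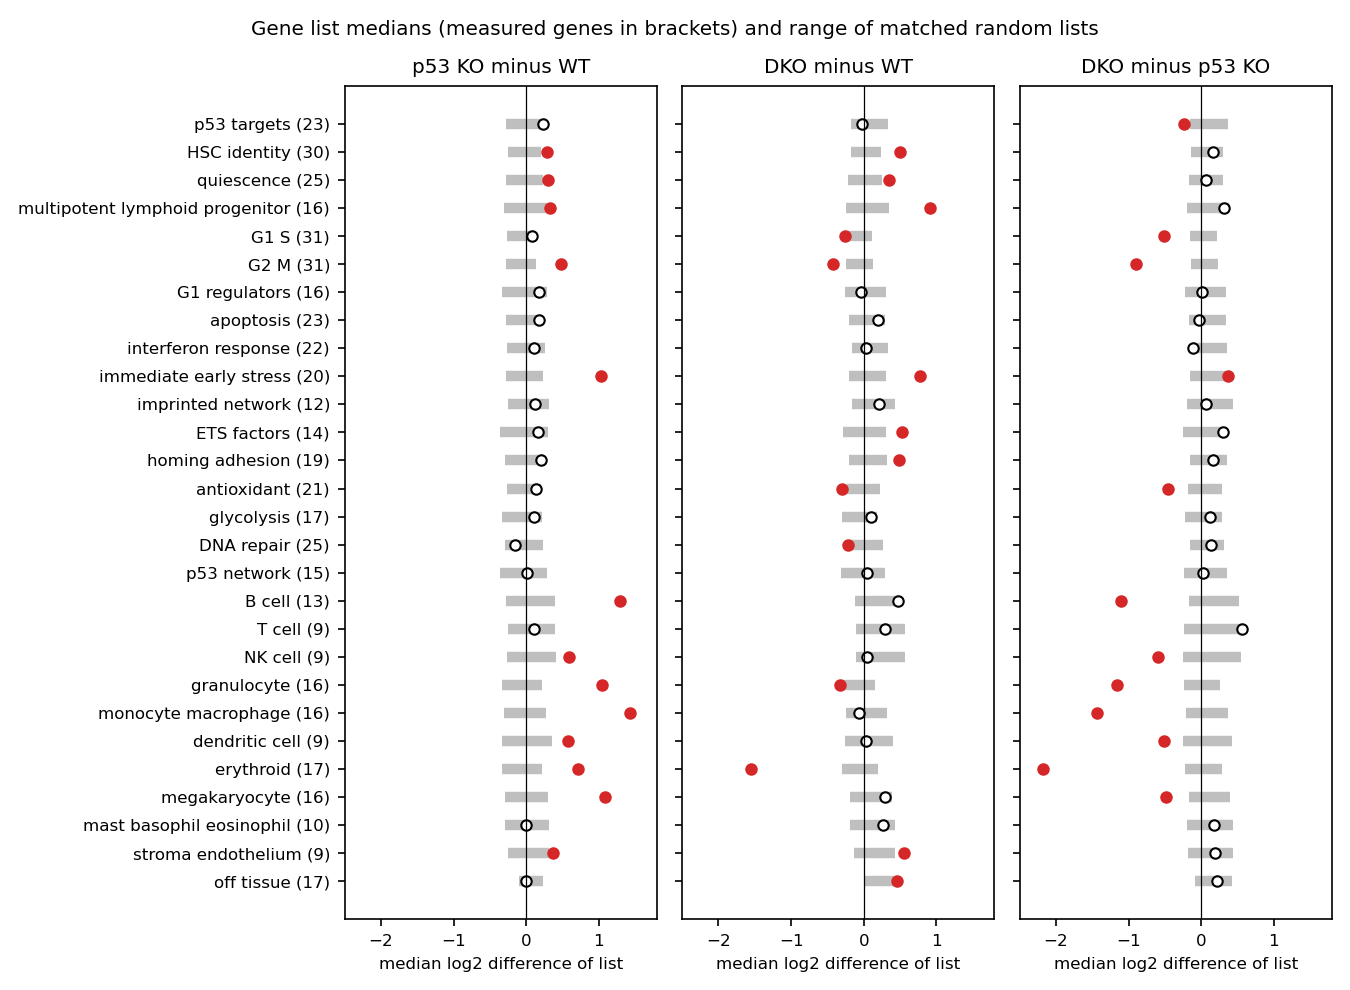
Median log2 signal difference of each gene list in the 3 comparisons, with measured genes in brackets. Grey bars span the middle 95% of 10000 matched random lists, filled points lie outside it and open points inside. The erythroid list lies farthest out, at -1.56 for DKO against WT and -2.18 for DKO against p53 KO.

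The DKO array was compared with the p53 KO array to ask what loss of Mef changes where p53 is already absent. Mature lineage markers and cell cycle genes were lower on the DKO array than on the p53 KO array. On that p53 KO array 7 of 9 mature lineage lists had been high against WT. Erythroid genes were the most reduced, all 17 being lower with a median of -2.18, and Ppbp was the most reduced gene, at 3292 on p53 KO and 118 on DKO (-4.81). Genes of G2 and mitosis were lower for 30 of 31 members, with a median of -0.90. Several progenitor genes were higher, among them Flt3, a receptor of multipotent progenitors, at 1492 on p53 KO and 4728 on DKO (1.66).

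Here 517 genes were at least 2-fold higher and 747 at least 2-fold lower. After Prm1 and Ccnb1ip1, with the same bounds as against WT, the highest were Nrip2 (2.48), the RNA polymerase subunit gene Polr3k (2.40), the receptor Pdgfrb (2.36), Car3 (2.29), Rgs1 (2.27), Slc25a17 (2.25), the germ cell helicase gene Ddx4 (2.21) and Cldn34c1 (at least 2.28). After Ppbp, the lowest were Apol8 (-4.11), the eosinophil gene Prg2 (-4.01), the red cell genes Epb42 (-4.00), Rhd (-3.84) and Kel (-3.59), Lrg1 (-3.56), Apol11b (-3.50) and Trim10 (-3.46), and Epx was lower by at least -3.85.

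Of the 29 lists, 1 lay above the middle 95% of random lists and 11 below it. Of the erythroid genes, 14 of 17 were at least 2-fold lower, including Alas2 at 11459 on p53 KO and 1091 on DKO (-3.39). Monocyte and macrophage genes had a median of -1.43 with 11 of 16 at least 2-fold lower, among them Ccr2 (-2.85) and the oxidase subunit gene Cybb (-2.61). Granulocyte genes were at -1.16 with 8 of 16, led by Mmp8 (-2.59), Mmp9 (-2.52) and Ltf (-2.46), and B cell genes at -1.10 with 8 of 13, led by Ebf1 (-1.76) and Blk (-1.75). These 4 lists lay below all random lists. NK cell genes were at -0.59 (percentile 0.110), dendritic cell genes at -0.51 (percentile 0.180) and megakaryocyte genes at -0.49 (percentile 0.0300, Tubb1 at -1.57), each outside in 6 of 7 alternative settings. T cell genes were at 0.55 (percentile 97.1), with the lineage factor Bcl11b at 1.56. Mast cell, basophil and eosinophil genes had a median of 0.17 but a mean of -0.54, since Cpa3 was at 2.02 and Prg2 and Epx were far lower, and with the floor at the 75th percentile the median was -0.58 (percentile 0.580). The 7 mature lineage lists that lay low here were all high for p53 KO against WT, and the same p53 KO array is reused here. DKO medians against WT were -0.06 (monocytes and macrophages), 0.48 (B cells), 0.05 (NK cells), 0.03 (dendritic cells) and 0.30 (megakaryocytes). Of the 7, only erythroid (-1.56) and granulocyte (-0.33, mean -0.01) lists were also low against WT. For the others, a property of the 1 p53 KO sample cannot be told apart from an effect of Mef loss.

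Both cell cycle lists were lower on the DKO array. In the list of G2 and mitosis 11 of 31 were at least 2-fold lower, such as Ube2c (-1.80), Kif11 (-1.53), the mitotic cyclin Ccnb2 (-1.40) and Prc1 (-1.40). G1 and S phase genes had a median of -0.51, with E2f2 at -3.22, Ccne1 at -1.63 and Rrm2, a ribonucleotide reductase subunit, at -1.39. Antioxidant genes were at -0.45, with Mgst1 (-1.39), Gclm (-1.20) and Gclc (-1.14) among 5 of 21 at least 2-fold lower. All 3 medians were below all random lists. G1 regulators had a median of 0.01, or -0.34 (percentile 1.58) with probe sets unique to a transcript, and a mean of -0.35, with Cdkn2d at -2.21, Ccnd3 at -2.0 and the retinoblastoma gene Rb1 at -1.70.

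The p53 target list was at -0.24 (percentile 0.745, outside in 4 of 7 alternative settings), with Gadd45a lower by at least -2.22 and Btg2 at -1.33, and its sign turned to 0.02 with the mean of all probe sets of a gene. Immediate early and stress genes were at 0.37 (percentile 98.3, outside in 5 of 7 alternative settings), with 3 of 20 at least 2-fold higher and 3 lower, Egr1 (1.72) and Jun (1.34) against Klf6 (-1.39). The progenitor list was at 0.31 (percentile 93.4), with Ctla2a at 1.99, Flt3 and Dntt (1.61) against Blnk (-1.68). Stem cell identity genes were at 0.16, with Cd34 at 1.44, the niche ligand gene Angpt1 at 1.12 and Hoxa9 at 1.04 against Pdzk1ip1 (-1.45). Quiescence genes were at 0.06 with a mean of -0.04, ETS factors at 0.29 (Ets1 at -1.45), and homing and adhesion genes at 0.16 with a mean of -0.07 (Itgb2 at -2.39). Interferon response genes were at -0.11 (percentile 4.55, but outside in 5 of 7 alternative settings, Rsad2 at -2.36), apoptosis genes at -0.04 (Bcl2 at 1.24, Bcl2l1 at -1.5), DNA repair genes at 0.13, glycolysis at 0.13, imprinted genes at 0.07 with a mean of -0.05, and p53 regulators at 0.03. The stroma and endothelium list was at 0.19, or -0.35 (percentile 0.625) with the floor at the 25th percentile, genes of other organs at 0.22 and sex-linked genes at 0.57.

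The median of all genes was 0.11 in this comparison and 0.01 after cyclic loess, which gave 317 higher and 877 lower genes (26.5% higher against 40.9%). With the floor at the 25th percentile the balance turned, to 1553 higher and 1200 lower (56.4% higher). Simulated unchanged arrays gave 255 to 314 per direction, but 1 of the noise models was taken from this same difference and cannot serve as its null. Further probe sets pointed the same way for 476 of 565 genes (84.2%). They were at least 2-fold the same way for 194 and at least 2-fold the opposite way for 3. Named genes with a probe set of opposite sign included Car3 (-0.67), Ccr2 (0.91), Ccnd3 (0.53), Kif11 (0.51) and Klf6 (0.31).

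Both p53-null arrays were set against the same WT array, which ties their differences together. Zmat3, Atp1b2, Zg16 (-3.28 and -2.45), Mt2 (-2.78 and -2.39) and Pvt1 were at least 2-fold lower on both, and Fos, Jun (1.03 and 2.37), Dntt (1.32 and 2.93), Gfi1 and Ndn at least 2-fold higher on both. In all, 129 genes were at least 2-fold higher on both, where independent sets would share 42.8 and simulated unchanged arrays shared 30.9 or 46.2, by noise model. The simulated sets were smaller, with 257 and 252 or 306 and 302 higher genes against 820 and 657 observed, and lower sets of 253 and 258 or 302 and 305 against 402 and 390, so simulated and observed shared counts are not directly comparable. For lower genes the numbers were 119 shared, 12.4 for independent sets and 119 or 94.6 in simulation, and 33 genes were at least 2-fold changed in opposite directions. Across genes the log2 differences correlated with r = 0.398 (rho = 0.430), below the 0.498 or 0.496 that a shared WT array gave in simulation. The covariance was 0.139 against 0.104 or 0.122 simulated, a difference of 0.0347 or 0.0169. A single WT array cannot be divided, so part of any excess may come from that array.

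**Figure D3:**
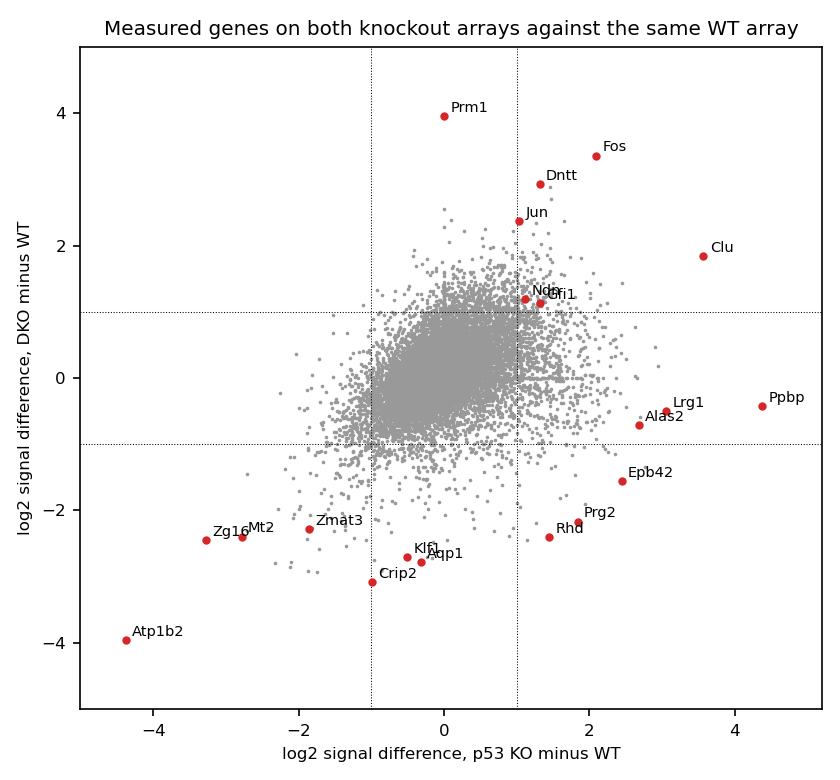
Log2 signal differences of 12597 measured genes, p53 KO minus WT on the horizontal axis and DKO minus WT on the vertical axis, 1 point per gene, with dotted lines at 2-fold. Atp1b2 lies lowest on both axes (-4.38 and -3.96), and Ppbp lies far right (4.38) but at -0.42 on the vertical axis.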

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

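The comparison of control probe sets and unnamed probe sets, and every test named here except that of signal-dependent scaling, were chosen after the results were seen. Spike-in RNA controls, which lie outside the gene comparisons, had a median log2 difference from WT of 0.34 on the p53 KO array and 0.54 on the DKO array over 17 probe sets, and 18 hybridization control probe sets had medians of 0.15 on both. Probe sets without a single gene name also held signal, 197 of 4435 being at least 2-fold higher and 99 lower on the p53 KO array than on WT, and 304 higher and 76 lower on the DKO array, with medians of 0 and 0.20.

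Markers of mature blood cells were higher on the p53 KO array than on the WT array, although sorting for LSK cells discards cells that carry mature lineage markers. More mature blood cells of several kinds in that sort stay open as the reason without a test that could have failed: the 7 of 9 mature lineage lists above the middle 95% of random lists are the pattern itself, and the 5 immunoglobulin genes (median 1.05, Igha at 20780 against 10068 on WT) were picked after Iglv1 and Ighg3 had stood out. Of 114 genes in these lists, 92 already reached the floor on the WT array and 6 stood in another list, but the WT sort may hold mature cells too and 9 of 33 genes of other organs also reached that floor. Against loss of p53 with or without Mef stand 0 of 9 lists above and 2 below for the array labelled DKO against WT, with medians of -0.062 for monocytes and macrophages, -1.56 for erythroid, -0.33 for granulocyte, 0.05 for NK and 0.03 for dendritic cells, Igha at -1.95, while B cells (0.48, or 0 with the 75th percentile floor) and megakaryocytes (0.30) were higher but inside, each outside with the mean of all probe sets, and 1 array whose label rests on no check cannot exclude it. An effect of p53 loss in cells that keep Mef, with a monocyte and macrophage median of 1.43 on the p53 KO array, cannot be told apart from the sort, since only 1 array holds that genotype.

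Genes of G2 and mitosis were lower on the DKO array than on the p53 KO array. Against WT their median was 0.48 on p53 KO and -0.43 on DKO, so both arrays contributed. Scaling that depends on signal is argued against, since after cyclic loess the median for DKO against p53 KO was -0.94 rather than nearer 0. Fewer erythroid progenitors on DKO, which divide often, may contribute, as its erythroid median against WT was -1.56, but the arrays give no share of cells per type. On the p53 KO array erythroid (0.71), granulocyte (1.05) and B cell (1.30) medians were higher than on WT. Loss of Mef, with a median of -0.90 for DKO against p53 KO, cannot be told apart from a difference in cell make-up with 1 array per genotype.

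Atp1b2, whose gene is next to that of p53, was 20.8-fold lower on the p53 KO array and 15.6-fold lower on the DKO array than on WT. A change across most of that region is argued against, as 0 of the other 19 nearest measured neighbours were at least 2-fold changed the same way on both arrays. Wrap53, on the other side of the p53 gene, had signals of 254, 306 and 272. Of the 20 neighbours with Atp1b2, 2 were at least 2-fold changed on each array. The rate over all genes would give only 0.39 changed the same way on both, so a change in a few genes there is not excluded. A fault of a lone probe set, such as a sequence difference carried with the targeted allele, could not be examined further, since the other Atp1b2 probe set reached 137 at most, close to the floor. An effect of the targeted allele or of p53 itself on Atp1b2 alone stays open and was not tested.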

How the results depend on the processing

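All settings here were planned. No paired analysis was possible because each genotype had 1 array, and for the same reason no array could be left out and no other split of the arrays exists. Rescaling to the trimmed mean moved nothing, since the arrays already shared that mean, and says nothing about stability. Numbers of genes are given as higher and lower for p53 KO against WT, then DKO against WT, then DKO against p53 KO. A floor at the 25th percentile gave 1531 and 895, 1861 and 755, and 1553 and 1200, and a floor at the 75th percentile 417 and 234, 202 and 233, and 159 and 465. The mean of all probe sets gave 518 and 245, 340 and 238, and 259 and 495. A threshold of 1.5-fold gave 1936 and 1571, 2157 and 1199, and 2140 and 1532, and one of 3-fold 230 and 64, 95 and 106, and 54 and 314. Cyclic loess left 432 higher for DKO against WT and 317 for DKO against p53 KO. The correlation between both comparisons with WT was 0.38 after quantile normalization and 0.42 with the 25th percentile floor. Genes higher on both p53-null arrays numbered 495 and 27 with the 25th and 75th percentile floors, 240 with a pseudocount and no floor, and 64 with the mean of all probe sets. Genes lower on both numbered 269 and 66 with those floors and 73 with that mean.

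Of 39 list medians outside the middle 95% of random lists, 1 changed sign under an alternative: the p53 target median for DKO against p53 KO, -0.24 as reported, was 0.021 with the mean of all probe sets. Of 254 values of named genes that were at least 2-fold, 1 changed sign: Rnf157 for DKO against WT, 2.37 as reported, was 0.54 with the mean of all probe sets and -0.24 with probe sets unique to a transcript. Among the other values, mostly close to 0, the sign changed in at least 1 alternative for 13 of 48 list medians and 3 of 132 of named genes. The cause was not tested for any change listed here, except that the floor and the threshold set by construction how many genes can pass. Of the other values of lists under an alternative, 481 moved less than the spread of random lists and 127 more. For the gene groups added after the values were seen, 99 moved less and 6 more. For named genes 2297 moved less than the spread between probe sets and 364 more. These counts leave out the rescaling that moved nothing. In all 7 other alternatives to scaling, floor and probe set, lists outside the middle 95% numbered 9 of 13 for p53 KO against WT, 7 of 14 for DKO against WT and 7 of 12 for DKO against p53 KO. Of the 48 list medians inside it as reported, 17 lay outside in at least 1 alternative. These were p53 targets, G1 regulators, homing, glycolysis and mast cell lists for p53 KO against WT, and glycolysis, B cell, megakaryocyte and sex-linked lists for DKO against WT. For DKO against p53 KO they were progenitor, G1 regulator, interferon, ETS, T cell, mast cell, stroma and sex-linked lists. Signal near the floor limits what can be said of dim genes, among them Elf4.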

Other observations

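The gene groups here were drawn up after the values were seen, and the tests of them were not planned. Genes of the nucleolus and of ribosome assembly were lower on both p53-null arrays than on WT, more so on the p53 KO array. On that array markers of mature cells were also higher, with medians of 1.43 for monocytes and macrophages and 1.30 for B cells against WT, and Kit signal was 2522 against 4996 on WT and 4873 on DKO. All 30 measured members were lower on p53 KO, 19 of them at least 2-fold, with a median of -1.09 below all 10000 random lists. Examples are Ncl, which encodes nucleolin (14725 on WT, 9173 on p53 KO, 11361 on DKO), the rRNA methyltransferase gene Fbl (10854, 5220 and 6730), Nop56 (4851, 1851 and 3193) and the polymerase subunit gene Polr1b (1866, 693 and 1203). On DKO 28 of 30 were lower than on WT, 3 at least 2-fold, with a median of -0.51, and all 30 were higher than on p53 KO, with a median of 0.52. A few members, Nme1, Ccdc86, Rrp9 and Utp14a, had been seen to be lower before the group was drawn up. Without these the median for p53 KO against WT was -1.07 over 26 genes, all lower. The group median stayed between -1.09 and -0.997 over the alternatives for p53 KO against WT. Myc, a known activator of such genes, had signals of 3532, 1624 and 3137 on the WT, p53 KO and DKO arrays.

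Other groups were less displaced for p53 KO against WT. The Gimap family, GTPases of lymphoid cells, had a median of 0.75 for DKO against WT (percentile 99.4, all 8 higher), though it was 0 in at least 1 alternative, and 0.23 for p53 KO against WT. Targets of ATF4, the amino acid stress factor, had medians of -0.03, -0.21 and -0.02 in the comparisons p53 KO with WT, DKO with WT and DKO with p53 KO, with Asns at 7258, 3082 and 1363 and Phgdh at 5616, 2977 and 8032 on the WT, p53 KO and DKO arrays. Cholesterol synthesis genes had medians of -0.11, 0.13 and 0.28 in the same order.

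Prm1 was read by 3 probe sets, of which 2 gave 1718 and 1697 on DKO against 3.48 and 2.35 on WT, and the other gave 370 against 108. None of these probe sets was among those unique to a transcript. The pancreatic elastase gene Cela1, on the list of genes of other organs, had signals of 3063, 853 and 728 on the WT, p53 KO and DKO arrays. Xist had signals of 245, 242 and 423, and the Y-linked gene Eif2s3y 2403, 2564 and 3658, both over the floor on each array.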
